A study of Bos taurus with 6 samples.

How the data were processed

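Gene expression was measured in cumulus cell biopsies of cattle (Bos taurus) on arrays read in Cy3 and Cy5. Per the labels' protocols, RNA was extracted with a kit for very small samples, amplified by T7 RNA polymerase over 2 rounds, and labelled by direct coupling of the dyes to the amplified RNA. The deposited files give, per the file headers, the mean foreground and the median local background intensity of each of 45212 spots in both channels, with no normalization. The scanner software is not given in the sources used here. The channel at the longer wavelength was read as Cy5. Each file also held 22 lines of summary statistics, which were left out. The deposited value table holds log2 ratios of 43674 probes, and its processing is not given in the sources used here.

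The value table was set against the scanner values after background subtraction and loess. Its columns correlated with the log ratios at sizes of r from 0.91 to 0.995 and slopes from 0.917 to 1.42. In sign, all 6 columns ran as CC-2-8-cells over CC-Blast by the dye labels. Column medians were -0.00115, -0.00999, 0.00423, 0.0134, 0.00459 and 0.00418, so the columns are centred. Centring was settled this way, and so was the scale of all columns but 1, with sizes of slope from 0.917 to 1.004. The slope of 1.42 and the r of 0.91 belonged to 1 array with CC-Blast in Cy3, called pair 3 below. The scale of its column was not settled. The direction is that of the dye labels, and the design text calls CC-2-8-cells the reference, which leaves open whether the dyes or the table's direction are as intended. No columns of other samples were present.

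Background was corrected with limma's normexp (offset 50) on all spots, and log2 ratios of Cy5 over Cy3 were normalized within each array by loess, with control spots and outlier-flagged spots at weight 0. Between 8 and 205 spots per array carried an outlier flag and were left out. The sign was turned so that every ratio is CC-Blast over CC-2-8-cells. A probe was kept when its foreground was above the 95th percentile of 153 negative control spots in at least 3 of the 6 channels of either fate. Saturated probes numbered 9 to 53 per array in Cy5 and 0 to 2 in Cy3 and were kept. Bovine control transcripts spotted 10 times per array had a median SD of the log2 ratio between copies of 0.122 to 0.17.

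The design text gives 3 biological replicates per fate for 6 arrays in both dye orientations, so the dye swap was read as technical. Arrays with the same area number on the 2 slides were averaged. After subtracting the slide mean, same-numbered arrays correlated at 0.85, 0.80 and 0.73 across kept probes and others at -0.68 to 0.22. Deviations from a mean of 3 arrays sum to 0, which pushes the other values below 0, so part of this contrast is built in. Same-numbered arrays still had the highest value for every array, and the number was taken to pair the arrays. Without the subtraction, same-numbered arrays correlated at 0.63, -0.15 and 0.04, with the dye and slide effect left in the ratios. The labels do not say that pools come from separate animals, so p-values of single probes measure the spread between these pools. Camera with a preset correlation compares the genes of a list with all other genes. Its p-values rest on the spread across genes and do not show that the pools go the same way. The labels give CC-Blast as not cryopreserved on the slide with CC-Blast in Cy5 and as cryopreserved on the other slide, while the protocol has all biopsies frozen. The paired arrays go together, and the labels were used only for fate and dye.

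Each of the 3 pair values was fitted with limma's lmFit and eBayes against 0, with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. Probes were named from the platform annotation given for this work, in which 21790 probes have 1 gene symbol, 0 have several and 22004 have none. A gene is represented by its brightest kept probe. For gene lists, limma's camera with a preset inter-gene correlation of 0.01 was run on 1 probe per gene, adjusted over the 25 lists with at least 5 measured genes, and repeated with an estimated correlation and with fry. Of 793 list entries, 726 matched by symbol, 4 by a synonym from the RefSeq gene table (assembly ARS-UCD2.0), and 63 had no match. No genome build is named for the array, so no coordinates are given.

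Lists, tests and the naming rule were fixed before the data were examined. The rule takes, in each direction, the 10 named genes with the largest mean log2 change past the adjusted threshold with the same sign in all 6 arrays. Where too few pass, it fills up with genes at an unadjusted p under 0.05 and the same sign in all 6 arrays. Here all 20 came from the second part, out of 280 such genes. It also takes the 3 members of each list with the smallest p. Alternatives covered the background correction, the normalization, the filter on dim probes, the pairing, the replicate unit, each slide alone, the deposited log2 table, the moderation, the probe of a gene, the list test and leaving out each pair. A fit of 5 arrays without the array of high signal was added after seeing the data.

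The steps were tested on simulated arrays with the dye effects and the spread between pairs taken from the real ones and the brightness rebuilt from the normalized intensities. These arrays were dimmer, since 26647 probes passed the filter against 37331 real ones. Each probe had the same spread in all 3 simulated pairs. Of the real pairs, 1 spread more widely, with an SD over probes of 0.416 against 0.191 and 0.213. The rates hold for the simulated arrays only. Of 26647 simulated probes tested for CC-Blast against CC-2-8-cells, 21 of 100 probes changed by a log2 of 1 and 71 of 100 changed by a log2 of 2 were called at the adjusted threshold, with 3 of 26428 unchanged probes called. A list of 20 genes shifted by 0.5 among 10900 simulated genes was called by camera, and 0 other lists were. Noise was drawn for each probe on its own, so simulated genes were not correlated. The list result therefore does not test the preset correlation of camera on the real arrays. R 4.3.3, limma 3.58.1, statmod 1.5.0 and matplotlib 3.10.9 were used.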

Results

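Cumulus cells are the somatic cells that surround the oocyte in the ovarian follicle. Small biopsies of them were taken from bovine cumulus-oocyte complexes out of follicles of 2 to 6 mm, collected from abattoir ovaries. Each complex was then followed on its own through maturation, fertilization and embryo culture to day 8. The biopsies fell into CC-Blast, whose oocyte gave a blastocyst, and CC-2-8-cells, whose embryo stopped at a cleavage stage. Each RNA sample was a pool of 5 biopsies, and the design gives 3 pools per fate. The pools were compared directly on 6 arrays, 3 with CC-Blast in the Cy3 channel and 3 with CC-Blast in the Cy5 channel. Arrays at the same position of the 2 slides were averaged into 3 pairs of opposite dye orientation, called pair 1, pair 2 and pair 3, and n is the number of pairs. The median probe intensity was 174 to 212.4 in Cy5 and 230 to 275.9 in Cy3 on 5 arrays, and 701.3 and 734 on the pair 3 array with CC-Blast in Cy3. The number of arrays limits the precision. Of 43794 probes, 37331 were above the negative controls often enough to be tested, and they named 13800 genes.

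The comparison asks which cumulus transcripts, measured before maturation, differ with the later fate of the oocyte. Named genes were ranked by their ratio only among the 280 at an unadjusted p under 0.05 that had the same sign in all 6 arrays. Of these, the immediate-early genes EGR1 and FOSB, the keratin gene KRT8 and the meiotic chromosome gene SYCP3 had the most negative ratios, and the calcium-binding protein gene S100A4 and the Golgi mannosidase gene MAN1A1 had the most positive ones. None of them passed the adjusted test. EGR1 (probe EMBV3_11644) had a log2 ratio of -1.35 ± 0.31 (SD, n = 3), so its intensity was 2.55 times as high in CC-2-8-cells. S100A4 had a log2 ratio of 1.46 ± 1.10 (SD, n = 3), or 2.76-fold, with 0.19 in pair 2 against 2.16 and 2.03 in pairs 1 and 3. The direction, CC-Blast over CC-2-8-cells, rests on the dyes named in the labels. The deposited value table runs the other way on all 6 arrays, and every sign here would turn if that table were read as CC-Blast over the reference.

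On the positive side, MAN1A1, which trims N-glycans, had a log2 ratio of 0.97 ± 0.76 (SD, n = 3) by the brightest of its 3 probes, which ranged down to 0.36. The interferon-inducible genes HERC5 and RTP4 followed with 0.87 ± 0.47 and 0.68 ± 0.37. MEST, an imprinted gene, had 0.78 ± 0.61, and TCF21, a transcription factor of mesenchymal cells, had 0.65 ± 0.20. SFRP4, a secreted Wnt modulator, had 0.62 ± 0.17. YEATS4, a chromatin reader, had 0.59 ± 0.35, TPP2, a peptidase, 0.58 ± 0.32 and COQ6, an enzyme of coenzyme Q synthesis, 0.55 ± 0.25. TCF21 and SFRP4 varied least between pairs among these 10 genes.

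On the negative side, SYCP3 had a log2 ratio of -1.43 ± 1.16 (SD, n = 3), from -2.45 in pair 1 to -0.17 in pair 3, and it was above the negative controls in 3 of 6 CC-Blast channels and 5 of 6 CC-2-8-cells channels, so the size of this ratio and its rank are uncertain. The other SYCP3 probe kept had a mean of -0.0502. KRT8 had -1.20 ± 0.62 and FOSB -1.15 ± 0.66. The 3 FOSB probes ranged from -1.15 to -0.32, all negative. TARSL2, a threonyl-tRNA synthetase gene, had -0.94 ± 0.44, and DGAT2, an enzyme of triglyceride synthesis, had -0.82 ± 0.52, with its other probe at -0.00446. NT5E, which makes adenosine outside the cell, had -0.80 ± 0.61. The alpha-globin gene HBA had -0.79 ± 0.37, FBXO30, a ubiquitin ligase subunit, -0.79 ± 0.13 and the chloride channel gene CLIC3 -0.78 ± 0.37. FBXO30 lay between -0.94 and -0.70 in the 3 pairs.

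**Figure D1:**
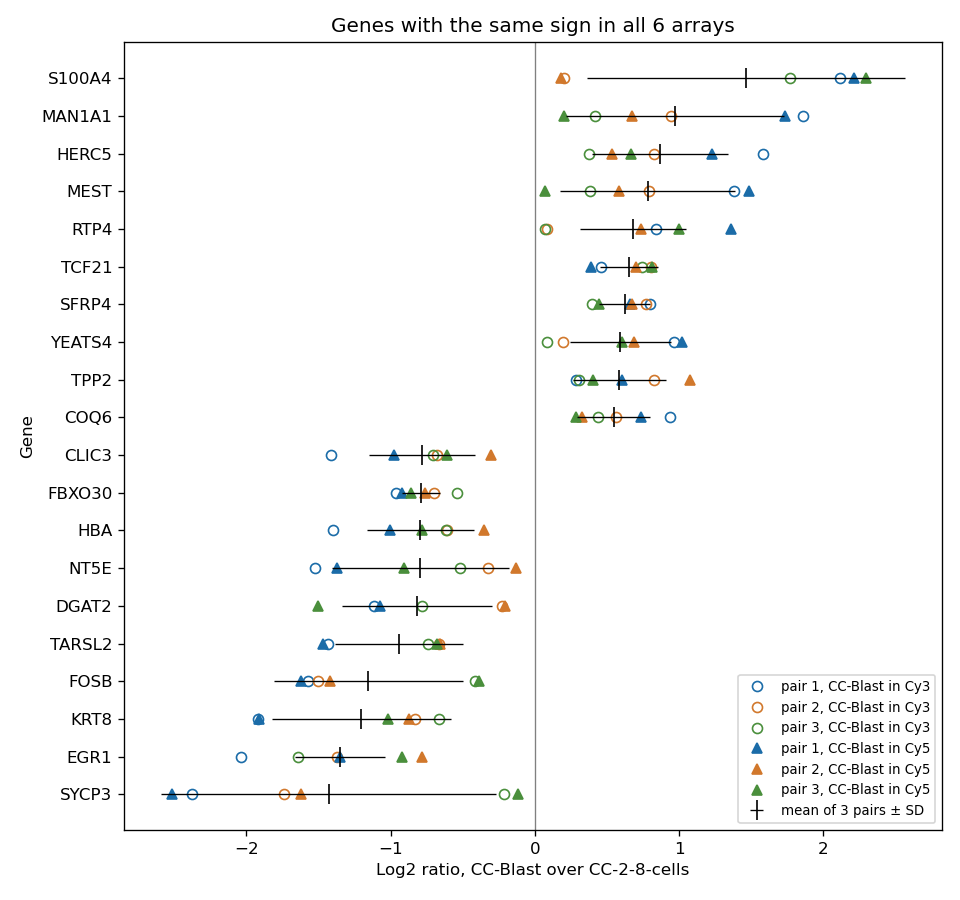
Log2 ratio of CC-Blast over CC-2-8-cells (x axis) for the 20 genes chosen by the naming rule (y axis). Circles and triangles are single arrays with CC-Blast in Cy3 and in Cy5, colours are pairs, and black marks are means of 3 pairs with SD. S100A4 lies at 0.19 in pair 2 and above 2 in pairs 1 and 3, while FBXO30 and TCF21 lie close together in all pairs.

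With limma's moderated test, 0 of 37331 probes passed an adjusted p of 0.05, and the smallest adjusted p was 0.871. At an unadjusted p under 0.05 there were 1318 probes, with 1867 expected by chance, and 52 of them also reached 1.5-fold, 13 higher and 39 lower in CC-Blast. With area as a random block over all 6 arrays the latter count was 92. Each slide holds 1 dye orientation only, so the dye and slide effect is not cancelled within it. There 453 probes (CC-Blast in Cy3) and 960 probes (CC-Blast in Cy5) reached an unadjusted p under 0.05 and 1.5-fold. On both slides 0 passed the adjusted threshold. Across kept probes, 28.4% had the same sign in all 3 pairs, against 25% by chance. Ratios of the 3 pairs barely went together across probes, which are not independent replicates (r = -0.07 for pairs 1 and 2, -0.24 for pairs 1 and 3 and 0.08 for pairs 2 and 3). Ratios of pair 1 had an SD of 0.416 over probes, against 0.191 in pair 2 and 0.213 in pair 3.

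**Figure D2:**
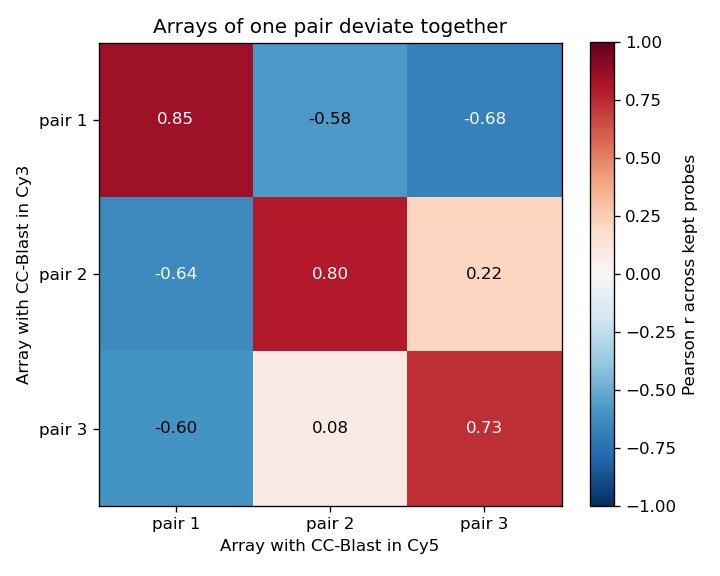
Pearson r across kept probes between each array with CC-Blast in Cy3 (rows) and each array with CC-Blast in Cy5 (columns), after subtracting the slide's mean log2 ratio. Arrays of the same pair reach 0.85, 0.80 and 0.73, and the highest value between different pairs is 0.22. The subtraction itself lowers the values between different pairs.

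Genes that respond to low oxygen were lower in CC-Blast as a group. Of 26 measured members of this list, 23 had a negative and 3 a positive mean ratio, with a median of -0.21, and limma's camera test with a preset correlation gave an adjusted p of 0.000139, against an adjusted p of 0.627 with an estimated correlation. CA9, a carbonic anhydrase, had a log2 ratio of -0.63 ± 0.22 (SD, n = 3), PFKFB3, a regulator of glycolysis, -0.55 ± 0.34, and MXI1, a MYC antagonist, -0.31 ± 0.18. The 3 probes of CA9 ranged from -0.63 to -0.0524, and those of MXI1 from -0.35 to 0.0309. These were the 3 members at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. The list median was -0.47 in pair 1, -0.06 in pair 2 and -0.06 in pair 3. Without pair 1 the camera adjusted p was 0.12.

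Cell cycle genes were higher in CC-Blast as a group. Of 42 measured members, 34 had a positive mean ratio, with a median of 0.08 (camera adjusted p = 0.00146, and adjusted p = 0.627 with an estimated correlation). The replication factors CDC6 and MCM7 had log2 ratios of 0.41 ± 0.21 and 0.28 ± 0.15, and the mitotic cyclin gene CCNB2 had 0.23 ± 0.13 (SD, n = 3). The other CDC6 probe had the opposite sign, at -0.0367. These 3 members were at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. The list median was -0.06 in pair 1 against 0.18 in pair 2 and 0.22 in pair 3. With median centring in place of loess the overall median was 0.18 (camera adjusted p = 0.0000163). The camera adjusted p was 0.102 without pair 2 and 0.191 without pair 3. Without pair 1 it was 4.9e-10, with a list median of 0.23.

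Immediate-early genes, which cells switch on quickly after a stimulus, were lower in CC-Blast as a group. Of 26 measured members, 16 had a negative mean ratio, with a median of -0.10 (camera adjusted p = 0.00525, and adjusted p = 0.627 with an estimated correlation). All 6 members at an unadjusted p under 0.05 were negative, among them EGR1, FOSB and the transcription factor gene KLF4 at -0.53 ± 0.24 (SD, n = 3). EGR1 was the 1 member that passed when adjusted over the list alone. The list median was 0.05 in pair 1, -0.28 in pair 2 and -0.26 in pair 3. The camera adjusted p was 0.172 without pair 2 and 0.181 without pair 3. Without pair 1 it was 4.0e-08, with a list median of -0.31.

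Genes of glycolysis were lower in CC-Blast as a group, with 17 of 25 measured members negative and a median of -0.08 (camera adjusted p = 0.0467, and adjusted p = 0.627 with an estimated correlation). PFKP, a phosphofructokinase, had -0.64 ± 0.13 (SD, n = 3) and was the 1 member that passed when adjusted over the list alone. The hexokinase gene HK2 had -0.83 ± 0.97 by its brightest probe, with 1 of its 3 probes of the other sign. The list shares SLC2A1, HK2, PFKFB3, PGK1, LDHA and PDK1 with the low-oxygen list, so both calls rest partly on the same genes. The glycolysis median was 0.10 in pair 1 and -0.12 and -0.09 in pairs 2 and 3. Its camera adjusted p was 0.273 without pair 2 and 0.223 without pair 3. Without pair 1 it was 0.00113, with a list median of -0.11.

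Interferon-response genes were higher in CC-Blast as a group, with 17 of 22 measured members positive and a median of 0.18 (camera adjusted p = 0.00305, and adjusted p = 0.627 with an estimated correlation). The antiviral genes ISG15 and OAS1 had 0.95 ± 0.96 and 0.61 ± 0.62, and the peptide transporter gene TAP1 had 0.20 ± 0.07 (SD, n = 3). The lowest of the ISG15 and OAS1 probes had 0.25 and 0.0549. TAP1 was the 1 member at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. TAP1 was negative, at -0.11, in the arrays with CC-Blast in Cy3 alone. The list median was 0.29 in pair 1, 0.11 in pair 2 and -0.05 in pair 3, and without pair 1 the camera adjusted p was 0.603.

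Genes of oxidative phosphorylation were higher in CC-Blast as a group, with 38 of 52 measured members positive and a median of 0.08 (camera adjusted p = 0.0298, and adjusted p = 0.627 with an estimated correlation). COX6C, a subunit of cytochrome oxidase, had 0.33 ± 0.24, and the ATP synthase genes ATP5F1 and ATP5C1 had 0.29 ± 0.24 and 0.26 ± 0.25 (SD, n = 3). No member was at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. The list median was 0.19 in pair 1, -0.04 in pair 2 and 0.05 in pair 3, and with median centring in place of loess the overall median was 0.15 (camera adjusted p = 0.00121). The camera adjusted p was 0.614 without pair 1 and 0.0787 without pair 3.

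These 6 of 25 lists passed with the preset correlation, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.627 for all 6. With fry, which tests whether a list's genes move one way on balance, the smallest adjusted p was 0.263 over all 25 lists. It belonged to the lists of cholesterol synthesis and of apoptosis and atresia. Among the 6 lists above the smallest fry adjusted p was 0.5125. With the preset correlation, over 22 alternatives to the reported fit, the low-oxygen list passed in 20, the glycolysis list in 14, and the cell cycle, interferon, immediate-early and oxidative phosphorylation lists in 18 each. Many of these alternatives, such as other pairings, keep the mean ratios, so the counts are not independent checks. The low-oxygen list did not pass without pair 1 (camera adjusted p = 0.12) or with CC-Blast in Cy5 alone (0.289). Within the slide with CC-Blast in Cy3, 2 lists passed camera, and within the other slide 0 did. The low-oxygen list had a median of -0.29 and of -0.12 within them, and the cell cycle list 0.07 and 0.12.

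**Figure D3:**
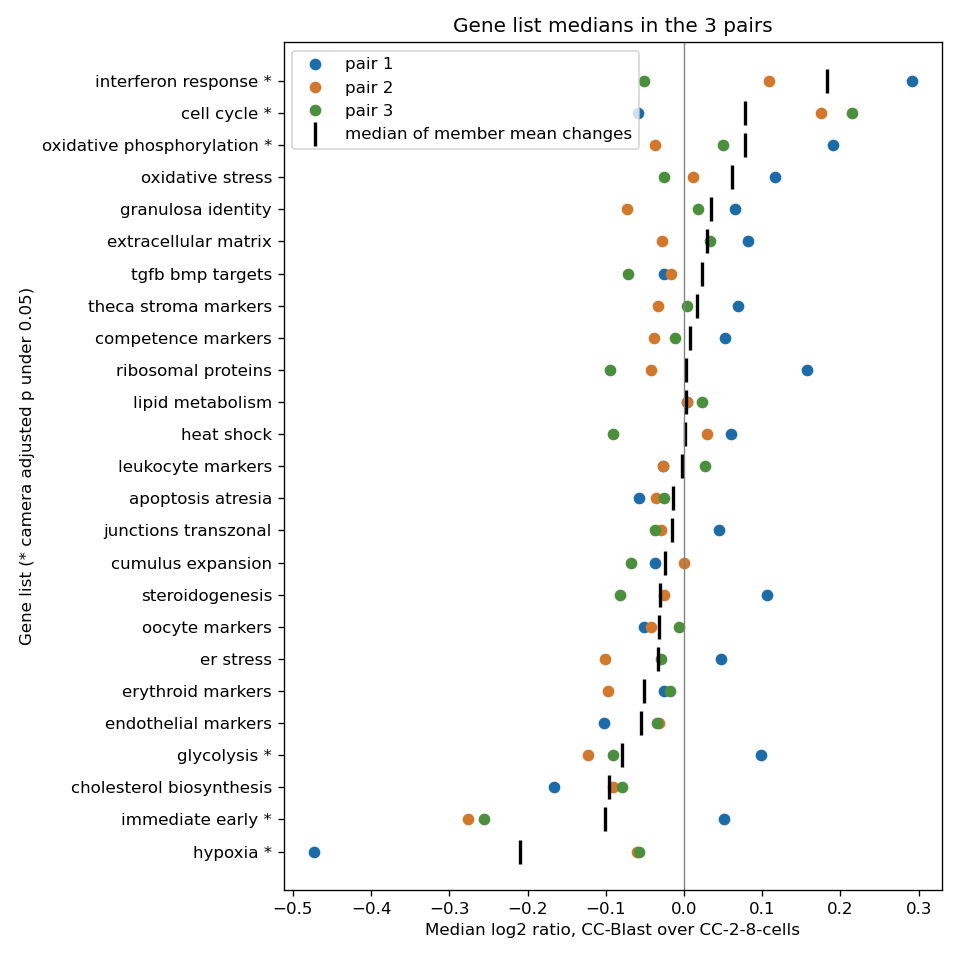
Median log2 ratio of CC-Blast over CC-2-8-cells (x axis) of each gene list (y axis). Dots are the 3 pairs, black ticks are medians of the members' mean changes, and stars mark lists past camera's adjusted threshold with the preset correlation. The low-oxygen list stands at -0.47 in pair 1 and near -0.06 in pairs 2 and 3.

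Cholesterol synthesis genes had a median of -0.10 with 12 of 20 members negative, and the list did not pass (camera adjusted p = 0.152). IDI1, which makes the isoprenoid building block, had -0.65 ± 0.27 (SD, n = 3), and SC5DL and SREBF2 had -0.35 ± 0.22 and -0.22 ± 0.13. SREBF2 was positive, at 0.12, in the arrays with CC-Blast in Cy5 alone. Steroid synthesis genes had a median of -0.03 (camera adjusted p = 0.638), with SRD5A1, a steroid reductase, at -0.46 ± 0.26. Cumulus expansion genes had a median of -0.02 (camera adjusted p = 0.344), with SDC4, a heparan sulfate proteoglycan, at -0.73 ± 0.63. Granulosa identity genes had a median of 0.03 (camera adjusted p = 0.638), with the receptor genes NPR2 and IGF1R at 0.34 ± 0.21 and 0.39 ± 0.26. Lipid metabolism genes had a median of 0.00277 (camera adjusted p = 0.906), with DGAT2 and the acyltransferase gene AGPAT9 at -0.82 ± 0.52 and -0.65 ± 0.44, and with other probes of both near 0, at up to -0.00446 for DGAT2 and -0.0175 for AGPAT9. Genes of apoptosis and atresia had a median of -0.01 (camera adjusted p = 0.464), with the apoptosome gene APAF1 at -0.21 ± 0.02.

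Heat-shock genes had a median of 0.00183 (camera adjusted p = 0.965) and their members went both ways. The chaperone regulators BAG3 and DNAJB4 had -0.38 ± 0.08 and -0.34 ± 0.12, and HSPA1A, the inducible chaperone, had 0.32 ± 0.16 (SD, n = 3). Endoplasmic reticulum stress genes had a median of -0.03 (camera adjusted p = 0.638). Oxidative stress genes had a median of 0.06 (camera adjusted p = 0.331), with GSTO1, a glutathione transferase, at 0.21 ± 0.10 and at 0.0035 by its other probe. Ribosomal protein genes had a median of 0.0031 and a mean of 0.10 (camera adjusted p = 0.331). Without pair 1 this list passed in the negative direction, with a camera adjusted p of 0.00182 and a median of -0.06, and without pair 3 it passed in the positive direction, with 0.00246 and a median of 0.06. Extracellular matrix genes had a median of 0.03 (camera adjusted p = 0.464), with LUM, a collagen-binding proteoglycan, at -0.87 ± 0.83. Targets of TGF-beta and BMP signalling had a median of 0.02 while camera pointed down (adjusted p = 0.985). Cell junction genes had a median of -0.02 (camera adjusted p = 0.97). In 1 of the 25 lists the median and the mean differed in sign, the lipid metabolism list, and in 2 the median and camera did, the leukocyte list and the TGF-beta and BMP list.

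A list of genes linked to oocyte competence in earlier cattle studies had 17 of 33 members positive, a median of 0.008 and a camera adjusted p of 0.906. KRT8 and AGPAT9 were negative and NPR2 positive, as given above. Some members may have been chosen on these same samples, so the list is not independent evidence of a direction. None of its members passed when adjusted over the list alone.

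Markers of other cells that a biopsy could hold passed no list test as reported, but with median centring in place of loess the oocyte and endothelial lists passed in the negative direction (camera adjusted p = 0.0131 and 0.00968). Oocyte markers had a median of -0.03 (camera adjusted p = 0.155), with the importin gene KPNA7 at -0.38 ± 0.08 and the transcription factor gene FIGLA at -0.16 ± 0.03 (SD, n = 3). The 3 KPNA7 probes ranged up to -0.0347. KPNA7 was positive, at 0.12, in the arrays with CC-Blast in Cy3 alone. Endothelial markers had a median of -0.06 (camera adjusted p = 0.169), and erythroid markers, which include HBA, -0.05 (camera adjusted p = 0.201). Theca and stroma markers had a median of 0.02 (camera adjusted p = 0.906), with TCF21 positive and the smooth muscle gene CNN1 at -0.38 ± 0.23. Leukocyte markers had a median of -0.00263 (camera adjusted p = 0.906).

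In the ratio of Cy5 over Cy3 averaged within pairs, 14703 probes, 39.4% of those tested, passed an adjusted p of 0.05 with limma. Dye and slide are the same split here, so the 2 cannot be told apart. Averaging within a pair cancels only a dye effect of the same size on both slides. A part that differs between the slides stays alike in the 3 pair means, and the SD between pairs does not show it. The median size of the dye and slide effect was a log2 of 0.11, against 0.08 for the fate. This count is not comparable with that for the fate, since its error is the spread of the sum of both arrays of a pair, in which differences between the pools cancel.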

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

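All tests of explanations in this part and in the observations were chosen after the pattern to be explained was seen. For the test of different probes of a gene and the test of oviduct markers, the bounds were written before the test value was read. The 6 arrays were compared for 8 array measures, 84 named genes and 25 list medians. In 7 of these 117 sets 1 array stood apart, where chance gives about 5.85. All but 1 of the 7 were array measures, and the other was a list median. The chance figure takes the 6 arrays as independent, which arrays of a pair are not for genes and lists. The total therefore does not speak for chance in the array measures. The gap between the array that stood apart and its nearest neighbour is given as a share of the whole range.

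The pair 3 array with CC-Blast in Cy3 had a median probe intensity of 701.3 in Cy5 against 174 to 212.4 elsewhere (gap 0.927), and of 734 in Cy3 against 230 to 275.9 (gap 0.909). Its negative control limits were 324.3 in Cy5 (gap 0.759) and 338.5 in Cy3 (gap 0.739), and 43392 probes were above the limit in its CC-2-8-cells channel against 32908 to 35012 (gap 0.799). The pair 1 array with CC-Blast in Cy3 had 205 outlier-flagged spots against 8 to 21 (gap 0.934). The median of oocyte markers was -0.18 on the pair 1 array with CC-Blast in Cy5, against -0.02 to 0.03 on the other 5 arrays (gap 0.736).

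The ratios of pair 1 spread more widely than those of the other pairs. Both arrays of this pair argue against noise of spots or hybridization as the source. Their ratios correlated at 0.63 across probes in opposite dye orientations. The same correlation was -0.15 in pair 2 and 0.04 in pair 3, with the dye and slide effect left in the ratios. If the position of a probe along an RNA shortened in amplification were the source, different probes of a gene would be unrelated. The 2 brightest probes of a gene correlated at 0.387 over 3412 genes in pair 1, between the bounds set for either outcome, and at 0.378 and 0.368 in pairs 2 and 3. Amplification therefore stays open, as do differences between the pooled animals, which the labels do not let be tested.

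The immediate-early genes EGR1, KLF4, FOSB, JUND, FOS and IER2, picked from their list by an unadjusted p under 0.05, had negative mean ratios, and EGR1 alone passed when adjusted over the list. The whole list had a median of -0.20 with CC-Blast in Cy3 (camera adjusted p = 0.00972) and of -0.0591 with CC-Blast in Cy5 (camera adjusted p = 0.315). A dye bias that is the same on both slides cancels in the means of pairs by the design, so it is not their source, and one that differs between the slides was not tested. A stress during handling shared with heat-shock genes would lower that list too. Its highest pair median was 0.0602 and its lowest -0.09, with members going both ways, so handling cannot be told apart from a difference tied to the fate, which stays open.

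With 3 pairs there are 4 ways to turn the pairs' signs, too few to exclude chance. The real direction gave 0 probes past the adjusted threshold, and the highest of the others gave 0, so all 4 gave as many. At an unadjusted p under 0.05 and 1.5-fold the real direction gave 52 probes and the highest other 322, with 3 of the 4 as large. For lists past camera's threshold the real direction gave 6 and the highest other 3, with 1 of the 4 as large.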

How the results depend on the processing

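Under all 21 alternatives for probes, 0 probes passed limma's adjusted threshold, with a smallest adjusted p of 0.119 and 586 to 8418 probes at an unadjusted p under 0.05. The count at an unadjusted p under 0.05 and 1.5-fold, 52 as reported, was 30 without background correction, 34 with plain subtraction, 90 with 6 separate arrays and a dye term, 92 with area as a random block, 98, 128, 132 and 115 with 4 other pairings of the swapped arrays, 453 with CC-Blast in Cy3 alone, 960 with CC-Blast in Cy5 alone and 103 with 5 arrays without the array of high signal, a fit chosen after seeing the data. Leaving out a pair gave 157 to 242. Lists past camera's threshold, 6 as reported, were 2 with CC-Blast in Cy3 alone, 0 with CC-Blast in Cy5 alone, 0 with an estimated correlation, 0 with fry, 5 with the deposited log2 table, 4 with a trended and robust moderation and 3 to 4 without a pair. Glycolysis was lost with that table (adjusted p = 0.0795), that moderation (0.246), median centring (0.163) and 1 other pairing (0.0902), the immediate-early list with that moderation (0.205) and the interferon list with median centring (0.0529). The ribosomal list passed with another pairing (0.0302), and cholesterol synthesis with area as a random block (0.0391) and 1 other pairing (0.0392). The probes with a dye effect, 14703 as reported, were 8974 with the strict filter, where fewer probes were tested, and 7329 to 13604 without a pair. The lowest correlation of same-numbered arrays was 0.809 without background correction and 0.815 with the strict filter. Other causes were not tested.

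No named gene passed under any of 22 alternatives, and 1819 of the gene values kept their sign. Many of these could not turn. Other pairings, 6 arrays with a dye term or a random block, and another moderation keep the mean ratio where no array is missing. A between-array adjustment of the intensities alone keeps it too. Kept signs and unmoved list medians under these settings were fixed in advance and do not show robustness. With CC-Blast in Cy3 alone, HSD11B2 turned to 0.16, PTGER4 to 0.0821, GREM1 to 0.11, KPNA7 to 0.12, BOLA-DQA1 to 0.21, S100A8 to 0.01998, EGFL7 to 0.24, LHCGR to -0.37, CASP8 to -0.0626, MMP19 to -0.13, EIF2AK3 to -0.10, FABP5 to -0.12, TAP1 to -0.11, S100A9 to -0.0867 and ENG to -0.16. With CC-Blast in Cy5 alone, SREBF2 turned to 0.12, SKIL to 0.20 and PRDX5 to -0.0183. PTGER4 turned to 0.0414 with plain subtraction and 0.06998 with the strict filter, and ACTN4 to 0.00844 with the median of all probes. Within 1 dye orientation the dye and slide effect is not cancelled, so the values of these fits hold it by design. The cause of the turns under the other settings was not tested. Of the list medians, 513 moved by less than the SD between pairs and 36 by more, and none of the 6 lists past the threshold as reported changed sign. The ribosomal list passed in opposite directions without pair 1 and without pair 3.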

Other observations

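Against the spread between both arrays of a pair, which is technical, 11964 of 37110 probes (32.2%) differed between pairs at an adjusted p of 0.05 with limma, and 7766 of these stood farthest apart in pair 1. Separate pools are expected to exceed technical spread, and the count is not comparable with that for the fates, which rests on the spread between pairs. Both pools of a pair enter each ratio, so which pool differed is not known. The genes in this part were chosen after their values were seen. In pair 1 the antioxidant enzyme gene GPX1 had a log2 ratio of 2.07, against -1.35 and -1.60 in pairs 2 and 3, and ALDOA, an enzyme of glycolysis, had 2.06 against -0.90 and -0.64. CYP11A1, which starts steroid synthesis, had 1.60 in pair 1 and -1.02 and -0.99 in the others. In pair 2, MIF, a cytokine, had -1.72 against 0.72 and 0.47, and CARTPT, a peptide made in bovine follicles, had 2.07 against 0.75 and -0.91.

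The class II histocompatibility genes BOLA-DQB and BOLA-DYB had log2 ratios of -2.07 and -1.63 in pair 1, 0.46 and 0.68 in pair 2 and -1.09 and -1.09 in pair 3. The other 9 class II probes kept, CD74 and BOLA-DQA1 among them, lay between -0.21 and 0.24 in pair 3. In pair 1 BOLA-DMA went the other way, at 0.74, and the rest with a value lay between -0.25 and 0.01. Where a mean log2 intensity was given these 9 probes were dim, at 6.75 to 8.64, against 11.79 for BOLA-DQB and 9.97 for BOLA-DYB. The ratios near 0 therefore do not show that these genes did not follow. Of the 3 probes of INSIG1, a feedback gene of cholesterol synthesis, the brightest had -0.30, 0.08 and -1.24 in pairs 1, 2 and 3, and the others were negative in all pairs, with means of -1.09 and -0.56.

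In pair 3 the HOX genes HOXA9, HOXD10 and HOXD11, which mark posterior positions of the body, had log2 ratios of 3.11 and 2.39 for the 2 HOXA9 probes, 2.48 for HOXD10 and 2.96 for HOXD11. Their CC-2-8-cells signals in pair 3 were above the negative controls in 8 of 8 channels but low, at 1.002 to 1.994 times the limit, so the sizes of these ratios are uncertain. HOXD10 was above the limit in only 2 of 6 CC-2-8-cells channels. These 4 were the only ones of 18 HOX probes over 1 in pair 3, where the median of all was 0.14. HOXA3 lay just under 1, at 0.9985, with -1.47 in pair 2, HOXB8 and HOXA2 had 0.48 and 0.40, and HOXA10, HOXB9 and HOXC12 had 0.17, -0.0238 and -0.104. In pair 2 the 4 probes lay between 0.00136 and 0.03, and in pair 1 HOXD10 had 0.80, HOXD11 0.72 and the HOXA9 probes -0.00998 and 0.0797. Noise as the source was not tested apart from the values by which these genes were picked. Oviduct epithelium carried over into a pool may be thought of as a source. The median of 12 oviduct markers, OVGP1 and PAX8 among them, was -0.0347 in pair 3 with 0 of them over 1. These markers were dim, at mean log2 intensities of 6.99 to 8.19, and the 4 HOX probes lay at 7.416 to 7.985. Whether the marker probes could show carried-over tissue was not tested, so their ratios near 0 do not exclude this source. A difference between the pooled animals or cells stays open and was not tested.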
